A study of Mus musculus with 4 samples.

How the data were processed

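Single-cell RNA sequencing was run on dissociated ipsilateral brain hemispheres of wild-type mice after ischemic stroke, with 4 libraries in 4 groups and 1 library per group. Per the labels, hydrogel microspheres were implanted into the infarct cavity at day 5 after stroke and tissue was taken at day 14. The group names are kept as in the labels: MAPS, UT EV+MAPS, IL-1a TNFa C1q EV+MAPS and IL-4 C1q EV+MAPS. The last 3 are written below as UT EV, IL-1a/TNFa/C1q EV and IL-4/C1q EV, and together as the EV libraries. The labels do not say how many animals went into each library. Healthy control mice named in the labels were not analysed here.

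The deposited matrices hold raw UMI counts per gene and cell barcode for 55357 genes. Per the labels' protocols, tissue was digested with collagenase IV, papain and DNase I, erythrocytes were lysed, dead cells were removed with magnetic beads. Libraries were made with 10x Chromium 3′ v3 chemistry. Per the file headers, the count matrices of the 4 libraries were written by Cell Ranger 8.0.1, whereas the submitters' processing notes name Cell Ranger 7.0.0, bcl2fastq 5.0.1, Seurat 4.1.0 and genome build GRCm39. Which of these versions made the counts is not settled by the files. The deposited barcodes were already limited to cells: the lowest UMI total of a barcode was 500 in 3 libraries and 1233 in IL-1a/TNFa/C1q EV.

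Cells with at least 500 UMIs, at least 300 genes and at most 20.0% mitochondrial UMIs were kept, and doublets were called per library with scrublet as implemented in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0). Called doublets were removed, 6.00% of the cells of MAPS, 3.97% of UT EV, 5.33% of IL-1a/TNFa/C1q EV and 5.60% of IL-4/C1q EV. Counts were scaled to 10000 UMIs per cell and log-transformed, 3000 variable genes were chosen per library and combined among genes seen in at least 10 cells, and 40 principal components with 15 neighbours went into Leiden clustering (igraph 0.11.9) at resolution 1, over the 4 libraries together and without integration. A cluster took the class with the highest mean log2 fold of its markers over the other clusters, provided that at least 3 markers were detected in at least 10% of its cells and were at least 1.5-fold higher than in the mean of the other clusters. A cluster stayed unnamed where its 10 leading genes held more markers of another class than of its own, or where its cells were shallow and none of its own markers led it. Marker lists, gene lists, thresholds for naming genes and the comparisons were fixed before the data were examined, except the comparison of IL-1a/TNFa/C1q EV with UT EV, the UMI floor set to that of IL-1a/TNFa/C1q EV in all libraries, and the clustering of the 3 EV libraries without MAPS, which were chosen after seeing the data. The scoring that turns markers into class names was also written after the data were at hand.

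Peripheral leukocytes were monocyte/macrophage, neutrophil, dendritic, plasmacytoid dendritic, T, NK, innate lymphoid, B, plasma and mast/basophil classes, and microglia and border macrophages were not counted among them. Vascular cells were endothelial, pericyte and smooth muscle classes. Shares carry exact Clopper-Pearson 95% intervals. For expression, raw UMIs were summed per library and class for the 13 classes with at least 50 kept cells in each library. They are given as counts per 1000000 UMIs of the class (CPM), with exact Poisson intervals for sums and exact conditional binomial intervals for ratios of sums. All intervals cover counting error only, and since no group has replicates there are no tests, p-values or counts of changed genes.

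A gene was named for a library and class when it had at least 200 UMIs in the class over the 4 libraries and at least 30 in the library where it was highest, and its CPM lay above (or below) that of each other library, with the 95% interval of the ratio to the nearest library entirely beyond 1.5-fold. Genes were ranked by the interval bound nearest 1. The first 4 higher and first 4 lower genes were taken for IL-4/C1q EV and the first 2 on each side for each other library, in the 4 classes with the most cells (microglia, oligodendrocytes, endothelial cells and T cells). Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes and markers of other classes were left out. So were the sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. From a gene list, at most the 4 members with the largest absolute log2 ratio were named.

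There were 25 gene lists: interferon response, MHC class I, MHC class II, chemokine ligands, leukocyte adhesion, pro-inflammatory mediators, alternative activation of the IL-4 type, disease-associated and homeostatic microglia, complement, phagocytosis and lipid handling, proliferation, angiogenesis, blood-brain barrier, extracellular matrix, pan, A1 and A2 reactive astrocytes, trophic factors, T helper and regulatory genes, cytotoxicity, neutrophil maturation and ageing, myelination, hypoxia and glycolysis, and dissociation stress. The value of a list was the median log2 ratio of CPM, with 1 CPM added to both sides, over members with at least 20 UMIs in the class, for lists with at least 5 such members. Its counting interval came from 1000 Poisson redraws of the summed UMIs. Its percentile was taken among 10000 random lists of the same size matched on mean expression, and describes these libraries only.

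Each share was recomputed with at least 1000 UMIs per cell, with at most 10% mitochondrial UMIs, without doublet removal, at resolution 2, with each library clustered alone and with cells thinned to 1000 UMIs. List medians and named genes were recomputed with median-of-ratios size factors, with TMM factors (edgeR 4.0.16 in R 4.3.3), with thinned cells, with each cell weighted equally, without doublet removal, with each library clustered alone, and, for list medians, with 10 CPM added. Both added settings were run on all 3 kinds of result. The rule for named genes was tested on simulated data with 200 genes changed by known folds in IL-4/C1q EV. Of genes raised or lowered 3-fold it recovered 94.0% of those simulated in microglia (10761 genes run), 94.0% in oligodendrocytes (7494 genes), 92.0% in endothelial cells (5327 genes) and 88.0% in T cells (5901 genes). Of genes changed 2-fold it recovered 66.0%, 42.0%, 50.0% and 36.0%, and of genes changed 4-fold 100%, 100%, 84.0% and 94.0%. It recovered 0% of genes changed 1.25-fold in each class and called 0 of the unchanged genes. The simulated counts of the 4 libraries were Poisson draws around a shared profile. Unchanged genes thus differed by counting error only, so that 0 is not a false-call rate for the real libraries. Transcript lengths and exon numbers came from a GENCODE annotation of build GRCm38, matched by gene identifier. No coordinates are given, because that build differs from the one named by the submitters. Figures were drawn with matplotlib 3.10.9.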

Results

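Brain hemispheres with a treated stroke cavity were read cell by cell to see which cells were present, and what they expressed, when microspheres carried no vesicles or vesicles from differently treated astrocytes. MAPS, UT EV+MAPS, IL-1a TNFa C1q EV+MAPS and IL-4 C1q EV+MAPS gave 1 library each. The last 3 are called UT EV, IL-1a/TNFa/C1q EV and IL-4/C1q EV here. With no replicates, no difference below has a replicate check, and a group cannot be told apart from the library, animal or run that stands for it. All intervals are 95% counting intervals.

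The libraries held 13920 barcodes in MAPS, 13076 in UT EV, 15138 in IL-1a/TNFa/C1q EV and 14592 in IL-4/C1q EV, with median UMIs per barcode of 4541, 2663, 2615 and 2462. Cell filters and doublet removal left 13003, 12259, 14179 and 13523 cells. MAPS cells also had more mitochondrial UMIs, with a median of 1.43% against 0.553% in UT EV, 0.546% in IL-1a/TNFa/C1q EV and 0.573% in IL-4/C1q EV. The lowest barcode of IL-1a/TNFa/C1q EV had 1233 UMIs against 500 in each other library, so that library lacks the small cells that the others keep. In turn, 789 kept cells of MAPS, 1228 of UT EV and 1251 of IL-4/C1q EV had fewer than 1000 UMIs.

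Clustering gave 42 clusters, of which 38 took a class name and 4 stayed unnamed. Unnamed cells made up 0.723% of MAPS, 12.2% of UT EV, 14.99% of IL-1a/TNFa/C1q EV and 10.6% of IL-4/C1q EV. Most of them lay in a cluster led by Saa3, Apoc1, Apoe, Ccl8 and C1qa, with 9 cells from MAPS, 1004 from UT EV, 1876 from IL-1a/TNFa/C1q EV and 1132 from IL-4/C1q EV. These genes are expressed by myeloid cells, so the myeloid and leukocyte shares of the EV libraries depend on where that cluster is put. Several classes were held by different clusters in MAPS and in the EV libraries. Microglia were held by clusters 0 and 1 in MAPS and by 2, 30, 31 and 33 in the EV libraries. T cells were held by 5 against 36, 37 and 38, NK cells by 18 against 35, endothelial cells by 16 against 17, oligodendrocytes by 9 against 25 and 26, and astrocytes by 7, 10 and 12 against 7. Among the EV libraries, microglia of UT EV and IL-1a/TNFa/C1q EV lay mostly in cluster 31, and those of IL-4/C1q EV mostly in 30 and 31.

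Blood-derived leukocytes enter the injured brain after stroke, and the share of cells of that kind differed among the 4 libraries. It was highest where the vesicles came from astrocytes given IL-1a, TNFa and C1q, and lowest with microspheres alone. The kinds of leukocytes differed as well. Neutrophils stood out with IL-4/C1q EV, dendritic and NK cells with IL-1a/TNFa/C1q EV, and T cells made up most leukocytes in MAPS. Peripheral leukocytes were 14.1% of cells in MAPS (13.5 to 14.7%), 16.3% in UT EV (15.6 to 16.9%), 25.0% in IL-1a/TNFa/C1q EV (24.3 to 25.8%) and 21.3% in IL-4/C1q EV (20.6 to 22.0%). Of immune cells they were 21.3%, 31.6%, 44.0% and 38.5%, and immune cells were 66.2%, 51.4%, 56.9% and 55.3% of all cells. The order of the 3 EV libraries held in every processing tried, whereas the place of MAPS below them did not hold at the higher cluster resolution, where UT EV was at 10.9%.

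Monocyte/macrophage-like cells were 0.738% of MAPS (0.598 to 0.901%), 5.69% of UT EV (5.28 to 6.11%), 5.94% of IL-1a/TNFa/C1q EV (5.55 to 6.34%) and 7.49% of IL-4/C1q EV (7.05 to 7.95%). Myeloid cells other than microglia and border macrophages were 1.58% of MAPS, 7.77% of UT EV, 11.002% of IL-1a/TNFa/C1q EV and 13.2% of IL-4/C1q EV. Neutrophil-like cells, carrying genes such as S100a8 and S100a9, numbered 28 in MAPS (0.215%, 0.143 to 0.311%), 59 in UT EV (0.481%, 0.367 to 0.620%), 102 in IL-1a/TNFa/C1q EV (0.719%, 0.587 to 0.873%) and 465 in IL-4/C1q EV (3.44%, 3.14 to 3.76%). The neutrophil share of IL-4/C1q EV was 16.0-fold that of MAPS (10.9 to 24.3), 7.14-fold that of UT EV (5.44 to 9.53) and 4.78-fold that of IL-1a/TNFa/C1q EV (3.85 to 5.98). The neutrophil-like cluster had a median of 1263.5 UMIs per cell, close to the floor of IL-1a/TNFa/C1q EV. With that floor set in all 4 libraries the ratios were 11.7, 6.41 and 2.35, so part of the gap to IL-1a/TNFa/C1q EV followed from its missing shallow barcodes.

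Dendritic-cell-like cells were 0.623% of MAPS (0.495 to 0.774%), 1.48% of UT EV (1.28 to 1.71%), 3.74% of IL-1a/TNFa/C1q EV (3.44 to 4.07%) and 1.93% of IL-4/C1q EV (1.70 to 2.18%). Plasmacytoid dendritic-like cells, a source of type I interferon, were 0 of 13003 cells in MAPS. That allows a share of up to 0.0231% (3 cells of the total), or 0.0284% by the exact interval. These cells made up 0.122% of UT EV, 0.599% of IL-1a/TNFa/C1q EV and 0.362% of IL-4/C1q EV. T-cell-like cells were 9.34% of MAPS (8.85 to 9.86%), 5.64% of UT EV (5.23 to 6.06%), 8.24% of IL-1a/TNFa/C1q EV (7.79 to 8.70%) and 4.35% of IL-4/C1q EV (4.01 to 4.71%). NK-like cells were 1.68%, 2.21%, 4.09% and 3.06%, and B-like cells 1.4997%, 0.636%, 1.71% and 0.680% in the same order. Innate lymphoid, plasma, mast, smooth muscle and neuron classes took no cluster in any library.

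Among resident cells, microglia-like cells were 52.0% of MAPS (51.1 to 52.9%), 34.4% of UT EV (33.5 to 35.2%), 31.2% of IL-1a/TNFa/C1q EV (30.4 to 31.9%) and 33.1% of IL-4/C1q EV (32.3 to 33.9%). Vascular cells were 1.33% of MAPS (1.14 to 1.54%), 11.7% of UT EV (11.2 to 12.3%), 7.88% of IL-1a/TNFa/C1q EV (7.45 to 8.34%) and 12.5% of IL-4/C1q EV (11.98 to 13.1%). They were made up of endothelial-like cells (1.08%, 10.2%, 6.92% and 11.1%) and pericyte-like cells (0.254%, 1.52%, 0.966% and 1.44%). Astrocyte-like cells were 13.9%, 6.04%, 3.15% and 4.54%, oligodendrocyte-like cells 4.95%, 9.89%, 9.06% and 6.52%, and their precursors 0.369%, 2.26%, 1.80% and 2.18%. Neuroblast-like cells were 8.57%, 2.57%, 1.96% and 2.48%, and fibroblast-like cells 0.5999%, 0.579%, 0.444% and 0.991%. Border-macrophage-like cells were 0.123%, 0.767%, 0.748% and 0.880%, and ependymal-like cells 0.715%, 1.08%, 1.54% and 1.48%. Choroid-plexus-like cells were 2.58%, 1.20%, 1.42% and 2.70%, and erythroid-like cells 0.0308%, 1.09%, 0.811% and 0.658%. The erythroid-like clusters were led by haemoglobin genes but also by microglial or endothelial genes such as Crybb1 and Cldn5. Shares of dissociated cells depend on which cells survive digestion, and the deeper MAPS library was apart from the EV libraries in nearly every class.

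**Figure D1:**
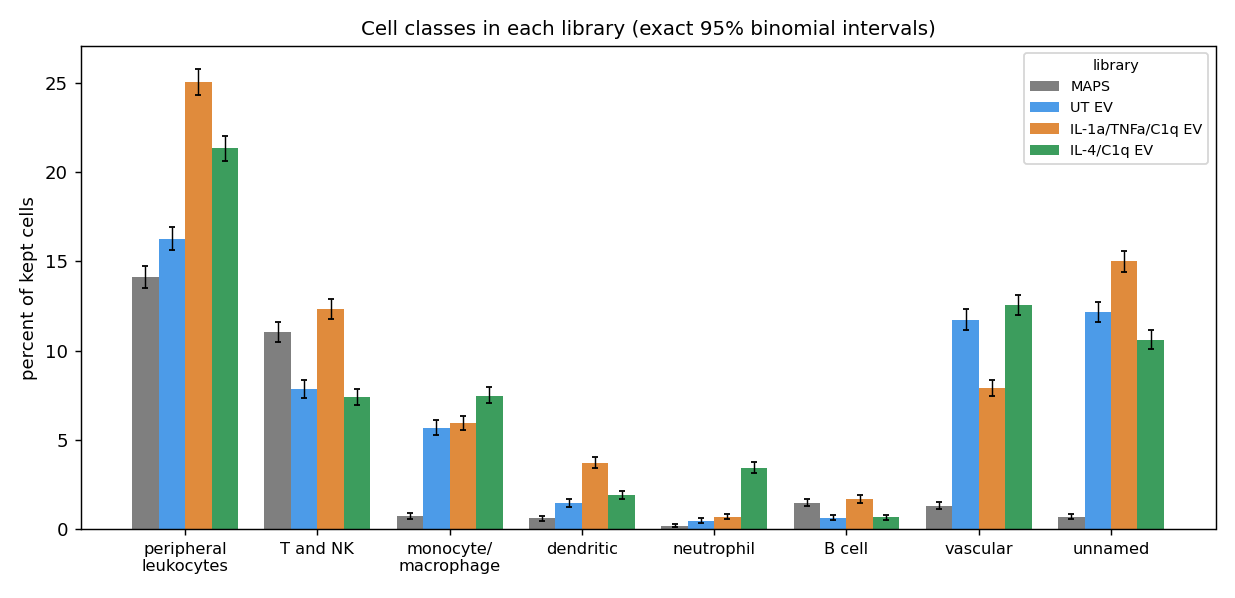
Share of all kept cells in percent per cell class and library, with exact 95% binomial intervals as bars (counting error only). Neutrophil-like cells reach 3.44% in IL-4/C1q EV against 0.719% or less elsewhere, and vascular classes are lowest in MAPS.

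Microglia of IL-4/C1q EV differed from those of UT EV most of all in genes that answer interferon, which were higher throughout. The genes of MHC class II, which present antigen to CD4 T cells, were lower, as were cell cycle genes and several chemokines that attract leukocytes. The interferon list was also higher than in UT EV in the other 12 classes measured, although the dendritic value turned with each library clustered alone and the choroid plexus one was small. The median log2 ratio of the interferon response list in microglia was 1.93 over UT EV, with 15 of 15 measured members higher and a percentile of 100 among random matched lists. Over IL-1a/TNFa/C1q EV it was 2.28, again with 15 of 15 members higher. Cluster 30, where many IL-4/C1q EV microglia lay, is itself led by interferon genes, so these medians compare all microglia of a library and include that mix of clusters. Over UT EV, Ifit3 (ENSMUSG00000074896), whose product restrains viral RNA, was 5.94-fold higher (5.29 to 6.70; 160 against 26.9 CPM), Oasl2 6.30-fold (5.09 to 7.87), Irf7 5.04-fold (4.34 to 5.89) and Ifitm3 4.30-fold (4.12 to 4.49; 942 against 219 CPM). Irf7 encodes the transcription factor that amplifies type I interferon production. Over IL-1a/TNFa/C1q EV, Oasl2 was 9.89-fold higher (7.53 to 13.2), Usp18 7.12-fold (5.65 to 9.09), Irf7 7.08-fold (5.90 to 8.56) and Rtp4 7.001-fold (6.19 to 7.95).

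MHC class II genes ran the other way in the microglia of IL-4/C1q EV. The list median was −0.77 over UT EV and −0.76 over IL-1a/TNFa/C1q EV, with 0 of 9 members higher in each and a percentile of 0. H2-Eb1 (ENSMUSG00000060586) stood at 0.246 of its UT EV level (0.222 to 0.273; 38.0 against 154 CPM), H2-Aa at 0.251 (0.229 to 0.274) and the invariant chain gene Cd74 (ENSMUSG00000024610) at 0.284 (0.272 to 0.296; 234 against 824 CPM). Against IL-1a/TNFa/C1q EV the ratios were 0.151 for H2-Eb1 (0.136 to 0.167), 0.163 for H2-Aa and 0.188 for Cd74. Oligodendrocytes, which should lack Cd74, held 92.1 CPM of it in UT EV, 92.2 in IL-1a/TNFa/C1q EV and 36.2 in IL-4/C1q EV, so free RNA from antigen-presenting cells adds to these values but is smaller than the gap. MHC class I genes, which interferon induces, were slightly higher, with medians of 0.20 over UT EV (9 of 10 higher) and 0.32 over IL-1a/TNFa/C1q EV (7 of 10 higher). Nlrc5, the transactivator of these genes, was 2.34-fold and 2.70-fold higher, and Tap1 1.46-fold and 1.72-fold.

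Chemokine ligand genes had a median of −0.20 over UT EV (5 of 19 higher, percentile 0.20) and −0.24 over IL-1a/TNFa/C1q EV (3 of 19 higher, percentile 0.02). The neutrophil attractant Cxcl2 was at 0.535 of its UT EV level (0.498 to 0.575) and Cxcl1 at 0.106, on 5 against 51 UMIs (0.0329 to 0.263), although neutrophil-like cells were most frequent in IL-4/C1q EV. The T cell attractant Ccl5 was at 0.356 (0.334 to 0.379) and the B cell attractant Cxcl13 at 0.419 of the IL-1a/TNFa/C1q EV level. With each library clustered alone the chemokine median over UT EV was 0.22, of the other sign. Proliferation genes had a median of −0.84 over UT EV (2 of 12 higher) and −0.41 over IL-1a/TNFa/C1q EV (2 of 12 higher), with Mki67 at 0.183 (0.0794 to 0.375) and Birc5 at 0.261 of the UT EV level.

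Genes of alternative activation, which IL-4 induces in macrophages, differed little in microglia, with a median of 0.08 over UT EV (6 of 10 higher, percentile 92.8) and 0.21 over IL-1a/TNFa/C1q EV (6 of 10 higher, percentile 95.2). The IL-4 receptor gene Il4ra was 1.21-fold higher than in UT EV (1.07 to 1.37) and Mrc1 1.60-fold higher than in IL-1a/TNFa/C1q EV (1.16 to 2.22). Pro-inflammatory mediator genes had medians of 0.00 (7 of 13 higher) and 0.05 (7 of 13 higher). Within them Tnf was at 0.587 (0.543 to 0.634) and Il6 at 0.659 of the UT EV level. Cybb, the core of the phagocyte oxidase, was 1.59-fold and the inflammasome gene Nlrp3 1.36-fold the level of IL-1a/TNFa/C1q EV. Disease-associated microglia genes had medians of −0.06 (5 of 18 higher) and −0.04 (8 of 18 higher), with Clec7a at 0.686 of its UT EV level, and homeostatic microglia genes −0.14 (1 of 12 higher) and 0.06 (8 of 12 higher). Over UT EV, the median was 0.07 for complement genes (9 of 12 higher; C4b 1.61-fold, 1.29 to 2.01) and −0.07 for phagocytosis and lipid handling (5 of 13 higher; the cholesterol exporter Abca1 1.38-fold, 1.29 to 1.48). It was −0.20 for trophic factors (3 of 12 higher; Pdgfb at 0.783) and −0.01 for hypoxia and glycolysis (5 of 14 higher; Ankrd37 1.88-fold, 1.46 to 2.45).

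Among genes apart from all 3 other libraries in the microglia of IL-4/C1q EV, the leading higher ones all belonged to the interferon response. Ifit3 was 5.59-fold the next level, that of MAPS (5.19 to 6.02), Ifi206 (ENSMUSG00000037849) 5.57-fold that of MAPS (4.63 to 6.70). Ifit3b (ENSMUSG00000062488) was 5.46-fold that of UT EV (4.20 to 7.19) and Ifitm3 4.30-fold that of UT EV. The leading lower ones were Cdk5rap1, a tRNA-modifying enzyme gene, at 0.290 of UT EV (0.190 to 0.432), Xlr4a at 0.253 of MAPS (0.119 to 0.479), Cd74 at 0.493 of MAPS (0.473 to 0.513) and Cxcl1 at 0.201 of IL-1a/TNFa/C1q EV (0.0599 to 0.538).

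Endothelial cells of IL-4/C1q EV shared the interferon difference, and their MHC class I genes were higher with it. Genes of vessel growth and of the blood-brain barrier were close to UT EV and somewhat higher than in IL-1a/TNFa/C1q EV, and genes for leukocyte adhesion showed the same order. The interferon median was 0.95 over UT EV and 2.09 over IL-1a/TNFa/C1q EV, with 14 of 14 members higher in each. Bst2 (ENSMUSG00000046718), which tethers budding virus to the cell, was 2.59-fold its UT EV level (2.49 to 2.69; 2874 against 1112 CPM) and Ifit3 2.47-fold (2.31 to 2.64; 964 against 390 CPM). Against IL-1a/TNFa/C1q EV, Ifit2 was 9.40-fold (6.81 to 13.3), Ifit3 7.28-fold (6.51 to 8.15), Irf7 5.34-fold and Ifit1 4.67-fold. MHC class I medians were 0.42 and 0.87 (10 of 10 higher in each), with Nlrc5 1.85-fold and 3.03-fold and Tap1 1.71-fold and 2.12-fold.

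Angiogenesis genes in endothelial cells had medians of 0.11 over UT EV (9 of 16 higher) and 0.30 over IL-1a/TNFa/C1q EV (13 of 16 higher). Adm, encoding the vasodilator adrenomedullin, was 2.08-fold its UT EV level (1.79 to 2.43), and the tip cell gene Dll4 was 1.34-fold (1.06 to 1.71) and 2.14-fold (1.59 to 2.92). Blood-brain barrier genes had medians of −0.01 (6 of 12 higher) and 0.28 (10 of 12 higher), with the lipid transporter gene Mfsd2a 1.35-fold and 1.58-fold and the glucose transporter gene Slc2a1 1.58-fold the IL-1a/TNFa/C1q EV level. Leukocyte adhesion genes had medians of −0.04 (4 of 9 higher) and 0.29 (7 of 9 higher). Sele, which slows rolling neutrophils, was 3.52-fold (1.67 to 8.28) and 5.37-fold (2.11 to 17.5), and Vcam1 1.54-fold (1.39 to 1.71) and 1.91-fold (1.70 to 2.15). With cells thinned to 1000 UMIs the angiogenesis median over UT EV was −0.03. IL-1a/TNFa/C1q EV also carried a trend with transcript length against UT EV, measured in microglia only. Medians there were 0.096 for the shortest and −0.21 for the longest transcripts, so the endothelial medians over IL-1a/TNFa/C1q EV may include such a trend. Apart from all 3 other libraries, IL-4/C1q EV had higher Zbp1, a sensor of nucleic acids, at 2.90-fold UT EV (2.49 to 3.39), Bst2, Ifit3 and Ifi44 (2.54-fold UT EV, 2.22 to 2.91). Ccl3 was lower, at 0.430 of UT EV (0.359 to 0.513), but microglia carry it at 3289 CPM or more in each EV library, so free RNA can set that value. The carbonic anhydrase gene Car4 was at 0.531 of MAPS (0.480 to 0.587), which became 1.02 with TMM factors.

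Myeloid cells outside microglia and border macrophages carried the interferon difference too. Some genes of IL-4-type activation were higher in the monocytes and macrophages of IL-4/C1q EV, though the list as a whole was close to UT EV. In monocyte/macrophage-like cells the interferon median was 1.15 over UT EV and 2.12 over IL-1a/TNFa/C1q EV (15 of 15 higher in each), with Ifit3 3.79-fold (3.29 to 4.39) and 8.25-fold (6.81 to 10.1) and Ifit2 4.33-fold (3.55 to 5.33) and 8.34-fold. MHC class II medians were −0.26 and −0.56 (1 of 9 higher in each), with Cd74 at 0.725 and 0.629. The alternative activation medians were −0.06 (6 of 13 higher) and 0.15 (9 of 13 higher), though Arg1, the arginase of repair macrophages, was 4.13-fold (2.498 to 7.16), Chil3 3.56-fold (2.24 to 5.87) and Il10 2.95-fold their UT EV levels, with Pparg at 0.387 (0.231 to 0.632). Mrc1 was 1.99-fold (1.67 to 2.37) and Clec10a 1.43-fold the IL-1a/TNFa/C1q EV level. The neutrophil maturation list was higher in this class as well, with medians of 0.68 (6 of 6 higher) and 0.54 (5 of 6 higher) and Mmp9, a matrix protease stored by neutrophils, at 3.66-fold (2.97 to 4.54) and 1.70-fold (1.46 to 1.99). The greater number of neutrophil-like cells in IL-4/C1q EV makes free RNA a possible source of that, and without doublet removal the median over UT EV was −0.11. With each library clustered alone the MHC class II medians were 0.74 and 0.015, of the other sign.

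Dendritic-cell-like cells had interferon medians of 0.89 over UT EV and 1.58 over IL-1a/TNFa/C1q EV (15 of 15 higher in each), with Isg15 2.49-fold UT EV (2.20 to 2.83) and Ifit3 4.32-fold IL-1a/TNFa/C1q EV (3.08 to 6.12). Their alternative activation medians were −0.12 (5 of 11 higher) and −0.18 (4 of 11 higher), and the T cell attractants Ccl22 and Ccl17 were at 0.677 of UT EV and 0.342 of IL-1a/TNFa/C1q EV (0.287 to 0.406). With each library clustered alone the dendritic interferon medians were −1.07 and −0.84, so this class depends on the clustering. The alternative activation median over IL-1a/TNFa/C1q EV was 0.055 with cells thinned to 1000 UMIs.

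Lymphocytes of IL-4/C1q EV combined the interferon difference with higher cytotoxic genes, those by which T and NK cells kill targets. In T-cell-like cells the interferon median was 0.82 over UT EV (14 of 15 higher) and 1.001 over IL-1a/TNFa/C1q EV (15 of 15 higher). Ifit3 was 2.52-fold UT EV (1.62 to 4.004) and Rtp4 3.87-fold IL-1a/TNFa/C1q EV (2.86 to 5.28). Cytotoxicity medians were 0.44 (9 of 10 higher) and 0.38 (8 of 10 higher), with Gzma 3.05-fold (2.59 to 3.61) and 3.75-fold (3.24 to 4.36) and Gzmb 2.69-fold (2.07 to 3.53) and 2.15-fold. Gzma is an NK marker and among the genes leading NK cluster 35, while Cd8a had 14 UMIs in T cells of IL-4/C1q EV. Free NK RNA or NK cells within the T cell clusters may add to these values, which was not tested. T helper and regulatory genes had medians of 0.13 (8 of 14 higher) and −0.07 (6 of 14 higher). The type 1 genes Ifng and Tbx21 were at 0.501 (0.439 to 0.571) and 0.456 of UT EV, Il10 was 2.01-fold UT EV (1.22 to 3.36), and Ikzf2, found in regulatory T cells, was 1.90-fold IL-1a/TNFa/C1q EV (1.62 to 2.23). Proliferation genes had medians of 1.06 over UT EV (10 of 12 higher; Cdk1 3.13-fold) and 0.16 over IL-1a/TNFa/C1q EV (9 of 12 higher), of which the former became −0.04 without doublet removal, −0.18 with 1 UMI floor and −0.43 with each library clustered alone. Apart from all 3 other libraries, T cells of IL-4/C1q EV had higher Bst2 (2.14-fold UT EV, 1.92 to 2.39), Isg15 (1.77-fold UT EV, 1.57 to 1.99) and Ifi27l2a (1.88-fold IL-1a/TNFa/C1q EV, 1.82 to 1.95) and lower Dnajb1, a heat shock cochaperone gene (0.434 of IL-1a/TNFa/C1q EV, 0.320 to 0.580).

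NK-like cells had interferon medians of 0.67 over UT EV (13 of 15 higher) and 1.49 over IL-1a/TNFa/C1q EV (15 of 15 higher), and cytotoxicity medians of 0.38 and 0.28 (8 of 10 higher in each). The pore-forming perforin gene Prf1 was 2.31-fold (1.61 to 3.37) and 2.46-fold (1.83 to 3.34) and Gzmb 1.61-fold and 2.76-fold. B-like cells had interferon medians of 2.53 and 2.68 (10 of 10 higher in each), while their proliferation median over IL-1a/TNFa/C1q EV was −1.23 (0 of 12 higher), with Ube2c at 0.0628 (0.0170 to 0.163). This class held 92 cells in IL-4/C1q EV and 78 in UT EV, with Ifit3 at 29 against 2 UMIs. Its median of all genes was 0.40 over UT EV and 0.12 over IL-1a/TNFa/C1q EV. Its cluster was also led by Jchain, a plasma cell marker, and the mix of B and plasma cells was not tested.

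In the glia and stroma of IL-4/C1q EV the interferon genes were again higher, astrocytes carried more reactive genes than in UT EV, and fibroblasts carried more matrix genes than in IL-1a/TNFa/C1q EV. Oligodendrocytes had interferon medians of 0.99 over UT EV (14 of 14 higher) and 0.71 over IL-1a/TNFa/C1q EV (12 of 14 higher), with Ifit3 3.01-fold UT EV (2.19 to 4.18) and Ifitm3 2.64-fold IL-1a/TNFa/C1q EV (2.27 to 3.07). Myelination genes were slightly higher, at 0.10 (10 of 10) and 0.28 (9 of 10), with the myelin gene Mobp 1.12-fold UT EV. Apart from all 3 other libraries, oligodendrocytes of IL-4/C1q EV had higher Ifitm3 (2.03-fold, 1.78 to 2.33), Ecrg4 (2.22-fold, 1.71 to 2.90) and Hsph1 (1.82-fold, 1.59 to 2.07), each against UT EV, and Hspa5, a chaperone of the endoplasmic reticulum (1.65-fold IL-1a/TNFa/C1q EV, 1.56 to 1.75), and lower Sgk1 (0.452 of UT EV, 0.381 to 0.533). Ifitm3 stood at 129.8 CPM in these oligodendrocytes against 10049 in endothelial cells, so free RNA can set it.

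Astrocytes had interferon medians of 1.46 over UT EV (13 of 14 higher) and 1.72 over IL-1a/TNFa/C1q EV (14 of 14 higher). Rtp4 was 4.25-fold (2.41 to 7.91) and 5.62-fold (2.77 to 12.9). The pan-reactive list had medians of 0.64 (11 of 12 higher) and 0.42 (10 of 12 higher), the A1 list 0.33 (10 of 11) and 0.22 (9 of 11), and the A2 list 0.56 (6 of 7) and 0.08 (5 of 7). Lcn2, a secreted marker of astrocyte reactivity, was 5.51-fold its UT EV level (2.65 to 12.8) but 0.358 of its IL-1a/TNFa/C1q EV level (0.245 to 0.516). It stood at 38.1 CPM in IL-4/C1q EV, 6.91 in UT EV and 106 in IL-1a/TNFa/C1q EV, where neutrophil-like cells, a strong source, held 1748 CPM and microglia 1.43. Vim was 1.86-fold IL-1a/TNFa/C1q EV (1.54 to 2.25), Serping1 of the A1 list 5.07-fold UT EV (1.87 to 17.1) and Tm4sf1 of the A2 list 2.82-fold (1.59 to 5.18) and 3.77-fold (1.87 to 8.41).

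Fibroblasts had interferon medians of 1.47 over UT EV and 2.82 over IL-1a/TNFa/C1q EV (14 of 14 higher in each), with Isg15 4.06-fold UT EV (3.41 to 4.85) and Ifit1 13.2-fold IL-1a/TNFa/C1q EV (5.94 to 36.5). Extracellular matrix genes had medians of −0.02 (7 of 15 higher) and 0.80 (14 of 15 higher). This class held 134 cells in IL-4/C1q EV, 71 in UT EV and 63 in IL-1a/TNFa/C1q EV. The median over IL-1a/TNFa/C1q EV may also include the trend with transcript length of that library. The collagen gene Col3a1 was 1.97-fold (1.72 to 2.25) and 3.02-fold (2.62 to 3.51), the protease inhibitor gene Timp1 was at 0.287 of UT EV (0.234 to 0.351), and the collagen crosslinker gene Lox was 3.32-fold IL-1a/TNFa/C1q EV (1.96 to 6.01). Interferon medians were 0.98 and 1.87 in neuroblasts (13 of 13 higher in each), 0.37 and −0.01 in choroid plexus (8 of 13 and 6 of 13) and 0.57 and −0.58 in ependymal cells (11 of 14 and 2 of 14). Ependymal Ifit3 was at 0.268 of IL-1a/TNFa/C1q EV (0.224 to 0.320), so against that library 11 of 13 classes had a positive median, from −0.58 to 2.82, compared with 13 of 13 against UT EV, from 0.37 to 2.53.

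**Figure D2:**
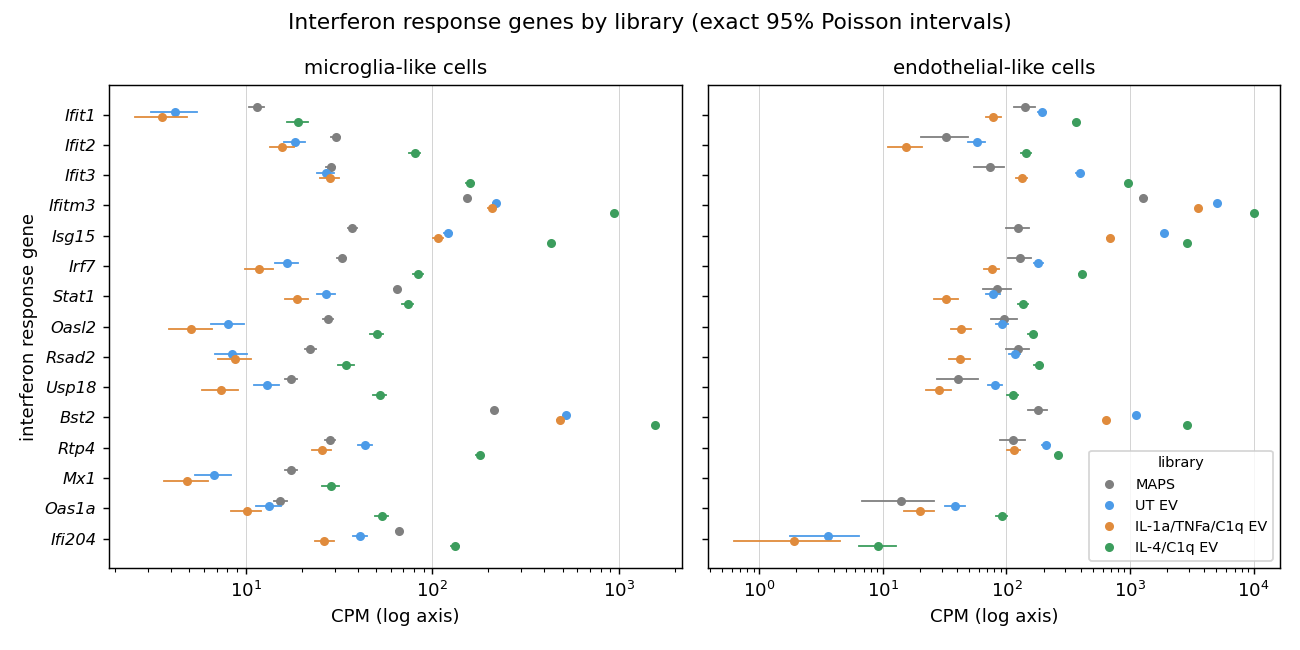
CPM on a log axis of the interferon response genes in microglia and endothelial cells of the 4 libraries, with exact 95% Poisson intervals as bars. Ifit3 stands at 160 CPM in microglia of IL-4/C1q EV against 26.9 in UT EV, and Bst2 at 2874 against 1112 CPM in endothelial cells.

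**Figure D3:**
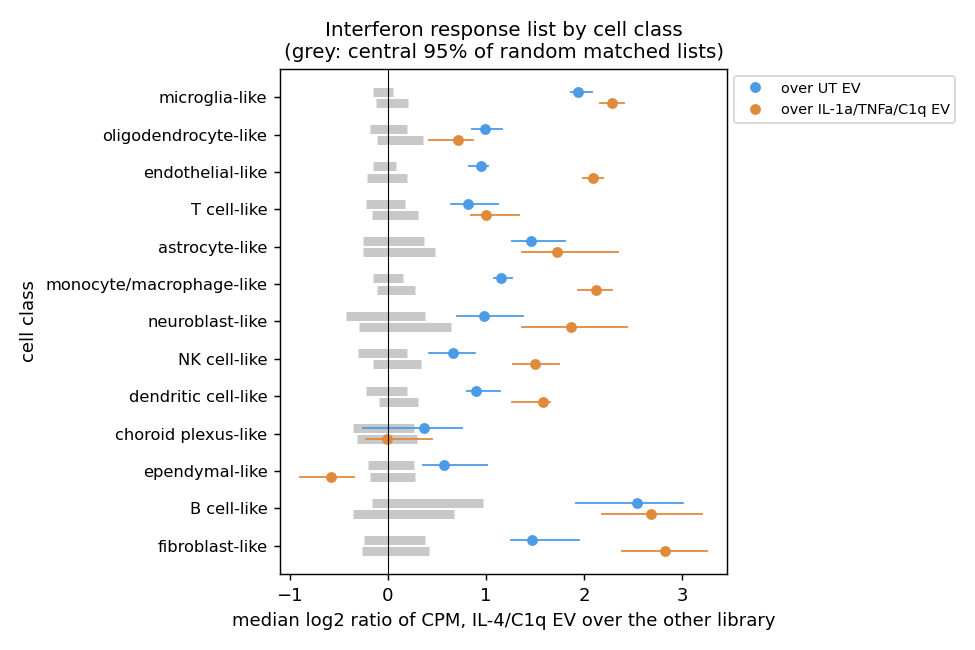
Median log2 ratio of the interferon response list in IL-4/C1q EV over UT EV and over IL-1a/TNFa/C1q EV in 13 cell classes, with thin lines for 95% counting intervals and grey for the central 95% of random matched lists. Microglia stand at 1.93 and 2.28, and ependymal cells at 0.57 and −0.58.

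Set against UT EV, the library with vesicles from IL-1a, TNFa and C1q astrocytes had lower interferon genes and higher MHC class II and chemokine genes in microglia, the reverse of IL-4/C1q EV in these lists. This comparison was added after the data were seen. It carries a trend with transcript length, with microglial medians of 0.096 for the shortest and −0.21 for the longest transcripts. The interferon median was −0.37 in microglia (2 of 15 higher, percentile 0) and −1.24 in endothelial cells (0 of 14 higher, percentile 0). Microglial Usp18 was at 0.565, Rtp4 at 0.587 and Oasl2 at 0.637. Endothelial Ifit2 was at 0.267, Ifit3 at 0.339, Usp18 at 0.351 and Rsad2 at 0.360. MHC class II genes had a median of 0.41 (7 of 9 higher, percentile 100), with H2-Eb1 1.63-fold, H2-Aa 1.54-fold, Cd74 1.51-fold and H2-Ab1 1.39-fold. MHC class I genes had a median of −0.12 (4 of 10 higher). Chemokine genes had a median of 0.20 (15 of 19 higher), with the monocyte attractant Ccl7 1.94-fold (1.65 to 2.28) and Ccl5 1.81-fold, and Cxcl2 at 0.561. Pro-inflammatory mediator genes had a median of −0.14 (6 of 13 higher), stress genes −0.39 (0 of 12) and proliferation genes −0.32 (1 of 12) in microglia, the last of which was 0.47 with each library clustered alone.

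In other classes of IL-1a/TNFa/C1q EV, cell cycle genes of B cells and astrocytic Lcn2 were higher than in UT EV. Interferon genes went both ways there. Ifit3 was higher in ependymal cells (538 against 119 CPM) and oligodendrocytes (32.1 against 10.3), and Bst2 in choroid plexus (701 against 375). Ifit3 was lower in monocyte/macrophage-like cells (21.6 against 47.0) and fibroblasts (74.4 against 146). Proliferation medians were 0.69 in T cells (11 of 12 higher) and 1.67 in B cells (12 of 12 higher). B cell Ube2c was 6.44-fold (4.0004 to 11.014), and the B cell median of all genes was 0.24. The T cell value became −0.20 without doublet removal and −0.23 with each library clustered alone. Astrocytic Lcn2 was 15.4-fold (7.79 to 34.6) within a pan-reactive median of 0.41 (9 of 12 higher), which was −0.55 with cells weighted equally. The fibroblast matrix median was −0.69 (1 of 15 higher), with Timp1 at 0.156 (0.111 to 0.216) and Postn at 0.209, on 63 fibroblasts against 71 in UT EV.

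Apart from all 3 other libraries, microglia of IL-1a/TNFa/C1q EV had higher G530011O06Rik (ENSMUSG00000072844; 1.78-fold UT EV, 1.54 to 2.05) and H2-Eb1 (1.63-fold UT EV, 1.54 to 1.73). Lower there were Brd1, a chromatin reader gene (0.262 of MAPS, 0.222 to 0.308), and Ifi44 (0.123 of MAPS on 3 UMIs, 0.0249 to 0.373). Endothelial cells had higher Cxcl2 (2.63-fold IL-4/C1q EV, 2.02 to 3.43) and Saa3, an acute phase gene (2.19-fold IL-4/C1q EV, 1.71 to 2.81), and lower Cmpk2 (0.277 of UT EV, 0.186 to 0.403) and Rsad2 (0.360 of UT EV, 0.288 to 0.446), both induced by interferon. Oligodendrocytes had higher Spp1 (3.69-fold UT EV, 3.41 to 3.998) and Fxyd7 (3.05-fold UT EV, 2.38 to 3.93) and lower Brd1 (0.334 of MAPS, 0.257 to 0.430) and Csnk2a2 (0.325 of IL-4/C1q EV, 0.233 to 0.448). T cells had higher Spp1 (3.14-fold IL-4/C1q EV, 2.75 to 3.60) and Saa3 (2.14-fold IL-4/C1q EV, 1.57 to 2.97) and lower Brd1 (0.307 of MAPS, 0.218 to 0.422) and Pmepa1 (0.444 of IL-4/C1q EV, 0.343 to 0.575). Spp1 stood at 12278 CPM in microglia and 10931 in monocyte/macrophage-like cells of this library, against 640 in T cells and 512 in oligodendrocytes, and Saa3 at 4444 CPM in its unnamed cells, so free RNA can set the Spp1 and Saa3 values of T cells, oligodendrocytes and endothelial cells. With each library clustered alone the Spp1 ratio of T cells was 0.956.

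UT EV had few genes apart from all 3 other libraries. Its microglia had higher Cxcl2 (1.63-fold MAPS, 1.55 to 1.72) and the linker histone gene H1f5 (2.11-fold IL-1a/TNFa/C1q EV, 1.66 to 2.69), and lower Slc15a2, a peptide transporter gene (0.231 of IL-1a/TNFa/C1q EV, 0.0918 to 0.514). Its oligodendrocytes had higher Cxcl10 (2.42-fold IL-1a/TNFa/C1q EV, 1.76 to 3.37), at 25.04 CPM against 198 in its microglia, so free RNA can add to it. Its endothelial cells had lower Depp1 (0.522 of IL-1a/TNFa/C1q EV, 0.434 to 0.626) and its T cells lower Cdca3, a mitotic gene (0.125 of IL-1a/TNFa/C1q EV, 0.0392 to 0.306). Ube2c ranked ahead of Cdca3 by the rule, but it defines a T cell cluster. H1f5 and Cdca3 took the other direction without doublet removal, at 0.950 and 1.27, as did Cxcl2 with each library clustered alone, at 0.428.

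Against MAPS, all 3 EV libraries had lower homeostatic genes in microglia and lower vessel growth genes in endothelial cells, while astrocytes had higher reactive genes. The interferon list was higher in IL-4/C1q EV microglia under every scaling, and in endothelial cells it was higher in UT EV as well. CPM values carry a shift here. The median log2 ratio of all measured genes in microglia was −0.61 for UT EV, −0.70 for IL-1a/TNFa/C1q EV and −0.67 for IL-4/C1q EV over MAPS. List medians are to be read against it. They also carry a trend with transcript length, with microglial medians for UT EV over MAPS of 0.86 for the shortest and −1.27 for the longest transcripts. Stress genes were lower in CPM than in MAPS in 13 of 13 classes. In endothelial and choroid plexus cells of UT EV, though, their medians (−0.52 and −0.39) lay above those of all genes (−0.68 and −0.99). The interferon median in microglia was −0.68 for UT EV (4 of 15 higher, percentile 44.9; 0.12 with median-of-ratios factors, so its sign depends on scaling), −1.15 for IL-1a/TNFa/C1q EV (3 of 15 higher, percentile 16.1; −0.28 with those factors) and 1.37 for IL-4/C1q EV (15 of 15 higher; 2.22 with those factors). Over MAPS, IL-4/C1q EV had Isg15 at 11.6-fold (10.98 to 12.3) and Bst2 at 7.26-fold (7.08 to 7.46). UT EV had Isg15 at 3.25-fold (3.02 to 3.49) with Oasl2 at 0.289, and IL-1a/TNFa/C1q EV had Isg15 at 2.87-fold with Oasl2 at 0.184. Homeostatic microglia genes had medians of −1.38, −1.62 and −1.38 over MAPS (0 of 12 higher in each), which stayed negative with median-of-ratios factors (−0.56, −0.67 and −0.50). Disease-associated genes had medians of −1.05, −1.10 and −1.22 (8, 6 and 7 of 18 higher). The homeostatic list was also lower in other classes of UT EV, at −1.85 in oligodendrocytes and −1.77 in endothelial cells (0 of 12 higher in each). In ependymal cells it was at −0.81 (1 of 12). All genes stood at −0.70, −0.68 and −0.62 in these classes. Microglia were 52.0% of cells in MAPS and 34.4% in UT EV, so free RNA from microglia can set the homeostatic values of these other classes.

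In endothelial cells, where the median of all genes was −0.68, −0.85 and −0.76 for UT EV, IL-1a/TNFa/C1q EV and IL-4/C1q EV over MAPS, interferon medians were 0.92 in UT EV (11 of 14 higher), −0.25 in IL-1a/TNFa/C1q EV (7 of 14 higher, percentile 42.4; 0.71 with median-of-ratios factors, so its sign depends on scaling) and 1.89 in IL-4/C1q EV (14 of 14 higher). Endothelial Isg15 was 15.1-fold MAPS in UT EV (12.2 to 18.9) and 23.5-fold in IL-4/C1q EV (19.1 to 29.4). Angiogenesis medians were −1.34, −1.62 and −1.38 (1, 3 and 1 of 16 higher), and −0.53, −0.68 and −0.50 with median-of-ratios factors. Those factors leave in the trend with transcript length, which was measured in microglia only. The longest transcripts there had medians of −1.27, −1.46 and −1.28 over MAPS, so the angiogenesis medians may include this trend. Flt4, a receptor of lymphatic growth factors, was at 0.296, 0.251 and 0.339. Blood-brain barrier genes of UT EV had a median of −0.86 (2 of 12 higher). T-cell-like cells of UT EV had lower cytotoxic genes than MAPS (median −2.08, 0 of 10 higher, against −0.68 for all genes; Gzmk 0.0640, 0.0384 to 0.1004; Prf1 0.0929). Their T helper genes were higher (1.15, 11 of 14), among them the chemokine receptor gene Ccr6 (8.30-fold). Most T cells of MAPS (1186) lay in cluster 5, led by Cd8a and Cd8b1. Those of UT EV lay mostly in cluster 37 (529 cells, led by Ctla4, Tnfrsf4 and Cd40lg) and cluster 38 (152 cells, led by Trdc and Il17a). These T cell values thus compare different kinds of T cells, and differences within a kind were not tested. T cell interferon genes of IL-4/C1q EV had a median of −1.02 over MAPS (4 of 15 higher, percentile 9.15). Astrocytic pan-reactive medians were 0.67 in UT EV (7 of 12 higher), 0.96 in IL-1a/TNFa/C1q EV (9 of 12) and 1.60 in IL-4/C1q EV (9 of 12). Hspb1 was 4.79-fold, 7.99-fold and 8.01-fold and Cp 7.14-fold, 7.67-fold and 9.05-fold. Different clusters held astrocytes in MAPS and in the EV libraries, so these values include a difference in cluster mix.

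In MAPS, the genes apart from all 3 EV libraries included noncoding and histone genes. Higher in MAPS microglia were the noncoding genes Gm11713 (ENSMUSG00000085245; 38.4-fold UT EV on 364 against 3 UMIs, 13.02 to 187) and Gm37376 (ENSMUSG00000102349; 16.5-fold UT EV, 11.8 to 23.6). Lower were the histone genes H2ac20 (0.0267 of IL-1a/TNFa/C1q EV, 0.0191 to 0.0366) and H3c6 (0.0373 of IL-4/C1q EV, 0.0272 to 0.0501), whose transcripts mostly lack poly(A) tails. MAPS oligodendrocytes had higher Gm37376 (23.9-fold IL-4/C1q EV, 15.3 to 39.3) and Dock9 (7.09-fold UT EV, 6.001 to 8.43) and had lower Gm12250 (ENSMUSG00000082292; 0.0477 of UT EV, 0.0172 to 0.106) and Cxcl12 (0.0385 of IL-1a/TNFa/C1q EV, 0.0153 to 0.0808). Oligodendrocytic Cxcl12 was 1.34 CPM in MAPS and 34.9 or more in the EV libraries, where endothelial cells, more frequent there, held 4322 or more. MAPS endothelial cells had higher Gm37033 (ENSMUSG00000104388; 9.90-fold IL-4/C1q EV, 7.41 to 13.3) and Csf1r (6.14-fold UT EV, 4.90 to 7.71), a microglial receptor gene at 269 CPM there against 3349 in MAPS microglia. Lower were Rn18s-rs5 (0.182 of IL-1a/TNFa/C1q EV, 0.176 to 0.188) and Isg15 (0.181 of IL-1a/TNFa/C1q EV, 0.144 to 0.224). MAPS T cells had lower Ccl20, an attractant of Ccr6-bearing cells, at 0.00771 of IL-4/C1q EV on 1 UMI (0.000188 to 0.0469). Cd8a, Cd8b1 and Il17a also passed the naming rule in MAPS T cells, but they define T cell clusters and are not given as results. The Ccl20 value too compares the different T cell clusters of MAPS and the EV libraries.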

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

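Tests of the MAPS pattern, of free RNA and of the UMI floor on interferon genes were written before their results were seen, and those of dissociation stress, of the neutrophil floor and of blood were chosen after. The test of intron reads was written after another test of the same pattern, leaving out the most abundant genes, had been run and replaced; that value is given among the other observations.

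Haemoglobin genes were left out of the naming of genes, whereas the ribosomal RNA gene Rn18s-rs5 was named above for MAPS endothelial cells. Both were flagged because their part of the UMIs in cells not named erythroid was above the level in MAPS, the library without vesicles. Haemoglobin genes held 0.189% of these UMIs in UT EV, 0.164% in IL-1a/TNFa/C1q EV and 0.115% in IL-4/C1q EV against 0.00622% in MAPS. Rn18s-rs5 held 2.39%, 1.84% and 2.58% against 0.223% in MAPS. Erythroid-like cells were also rarer in MAPS, at 0.0308% of cells against 0.658% or more in the EV libraries, though their clusters also carry microglial or endothelial genes.

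The MAPS library stood apart from the 3 EV libraries in all 13 classes, with correlations of log2 CPM of 0.472 to 0.882 against 0.877 to 0.992 between EV libraries. Transcript length is not the whole cause, since after its trend was taken out the SD of log2 UT EV over MAPS in microglia was still 3.19 times that of IL-1a/TNFa/C1q EV over UT EV (0.828 against 0.260), although the trend itself was strong, with medians of 0.86 for the shortest and −1.27 for the longest transcripts. Depth per cell is not either: with cells thinned to 1000 UMIs and equal totals the correlation of MAPS with UT EV was 0.778, against 0.988 between IL-1a/TNFa/C1q EV and UT EV. Intron reads counted differently could not make the gap in genes without introns, because over 716 genes with 1 exon the SD ratio was 3.98. These genes varied more between UT EV and MAPS than all microglial genes (SD 1.31 against 0.952), so they may not stand for the others. Vesicles and a library or animal difference may each lie behind what remains, and with MAPS as the lone library without vesicles they cannot be told apart.

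Interferon genes were higher in IL-4/C1q EV than in both other EV libraries in most classes. The stress list was not higher than in UT EV in microglia, with a median of −0.19 (−0.21 to −0.16). That argues against dissociation stress as the cause of the microglial gap to UT EV. The test was chosen after the data were seen and covers only the listed genes, so other handling differences stay open. Over the 13 classes the stress medians over UT EV ran from −0.97 to 0.29. Over IL-1a/TNFa/C1q EV the microglial stress median was 0.18, and stress is left open there. Free RNA from microglia is excluded as the sole source of 7 of 15 list genes in endothelial cells. Ifit1, Ifit3, Ifitm3, Isg15, Irf7, Rsad2 and Bst2 gained more CPM there than in microglia. For the other list genes it is left open, and 3 of them (Rtp4, Mx1 and Ifi204) gained more in microglia. Other classes were not tested for it, so part of their gain may be free RNA, whereas the UMI floor is excluded because with 1 floor in all libraries the microglial median over IL-1a/TNFa/C1q EV was still 2.28. A response to the vesicles or an interferon state of the animal could each give this, and only more animals could separate them.

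Neutrophil-like cells were most frequent in IL-4/C1q EV. The UMI floor of IL-1a/TNFa/C1q EV explains part of the gap to that library, as the ratio went from 4.78 to 2.35 with 1 floor in all libraries (1.85 to 3.002; 1.76% against 0.748%). Blood left in the tissue might add neutrophils, but T, NK and B cells together were −0.39 percentage points from UT EV (8.09% against 8.48%) while neutrophils were 2.96 points higher. Haemoglobin UMIs were lower than in UT EV too (0.115% against 0.189%), although erythrocytes had been lysed. The number of lymphocytes that come with each blood neutrophil was not measured, so blood cannot be ruled out, nor can recruitment in answer to the vesicles.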

How the results depend on the processing

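No paired analysis was possible because each group has 1 library. For list medians 116 results gave 1017 alternative values, of which 716 stayed within the counting interval, 286 moved beyond it and 15 took the other sign. For named genes the 470 alternative values of 62 results divided into 336, 126 and 8, and for shares the 465 of 60 results into 271, 194 and 0. The UMI floor of IL-1a/TNFa/C1q EV in all libraries and the clustering without MAPS were chosen after seeing the data. Unless a reason is given, the cause was not tested.

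The leukocyte share kept its order IL-1a/TNFa/C1q EV over IL-4/C1q EV over UT EV in every setting, but its size moved. With at least 1000 UMIs it was 14.9% in MAPS, 23.5% in UT EV, 34.3% in IL-1a/TNFa/C1q EV and 27.4% in IL-4/C1q EV, and with 1 UMI floor 15.02%, 23.3%, 33.5% and 24.7%. At resolution 2 it was 10.9% in UT EV, 18.1% in IL-1a/TNFa/C1q EV and 14.3% in IL-4/C1q EV. With each library clustered alone it was 12.7% in MAPS and 18.3% in UT EV. Without doublet removal it was 27.9% in IL-1a/TNFa/C1q EV and 19.0% in IL-4/C1q EV, and with the EV libraries clustered without MAPS 20.6% in UT EV, 31.7% in IL-1a/TNFa/C1q EV and 24.5% in IL-4/C1q EV. The vascular share was 10.4% in UT EV and 11.1% in IL-4/C1q EV with at least 1000 UMIs, 10.4% and 11.03% with thinned cells, and 9.81% and 10.3% with 1 UMI floor. Without doublet removal it was 12.5% in UT EV and 8.73% in IL-1a/TNFa/C1q EV.

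The interferon median of IL-4/C1q EV microglia stayed positive throughout. Over UT EV it was 2.12 with thinned cells and 1.56 with 10 CPM added; over IL-1a/TNFa/C1q EV 2.43 and 1.85. Over MAPS it was 2.22 with median-of-ratios factors, 2.09 with TMM factors, 1.64 with thinned cells, 1.73 with cells weighted equally, 1.16 with 10 CPM added and 1.253 with each library clustered alone. The added 10 CPM pulls low values toward 0 by construction.

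Values of the other sign came mostly from other cell assignments. With each library clustered alone, IL-4/C1q EV over UT EV gave 0.22 for microglial chemokines, −0.43 for T cell proliferation, 0.74 for monocyte/macrophage MHC class II and −1.07 for dendritic interferon genes; over IL-1a/TNFa/C1q EV the last 2 were 0.015 and −0.84. In the same setting IL-1a/TNFa/C1q EV over UT EV gave 0.47 for microglial and −0.23 for T cell proliferation, Cxcl2 of UT EV microglia was 0.428, Spp1 of IL-1a/TNFa/C1q EV T cells 0.956 and H1f5 of UT EV microglia 0.728. Without doublet removal T cell proliferation was −0.040 for IL-4/C1q EV and −0.20 for IL-1a/TNFa/C1q EV over UT EV, the neutrophil list in monocytes/macrophages −0.11, H1f5 0.950 and Cdca3 1.27. With 1 UMI floor T cell proliferation of IL-4/C1q EV over UT EV was −0.18 and H1f5 0.908, and without MAPS in the clustering H1f5 was 0.884. With thinned cells, endothelial angiogenesis over UT EV was −0.033 and dendritic alternative activation over IL-1a/TNFa/C1q EV 0.055. With cells weighted equally the pan-reactive median of IL-1a/TNFa/C1q EV over UT EV was −0.55, and with TMM factors Car4 of IL-4/C1q EV was 1.02 of MAPS. Depth limits which genes and lists are described. Genes with fewer than 200 UMIs in a class could not be named as apart from all other libraries. That floor did not apply to members named from a gene list, such as Rtp4 in astrocytes. Lists with fewer than 5 measured members were left out.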

Other observations

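Brd1 and Csnk2a2 were lowest in IL-1a/TNFa/C1q EV in every class, in some by few UMIs, and were singled out after their values were seen. Brd1, a chromatin reader gene, was lowest in IL-1a/TNFa/C1q EV in 13 of 13 classes, at 8.77 to 26.4 CPM, and highest in UT EV in 13 of 13, at 39.6 to 158 CPM. Csnk2a2, a catalytic subunit gene of casein kinase 2, was lowest in IL-1a/TNFa/C1q EV in 13 of 13 classes, at 2.67 to 20.3 CPM. No explanation was tested for either gene.

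Immediate early and heat shock genes of the dissociation stress list had negative medians in 12 of 13 classes for IL-4/C1q EV over UT EV, in 12 of 13 for IL-1a/TNFa/C1q EV over UT EV, in 2 of 13 for IL-4/C1q EV over IL-1a/TNFa/C1q EV and in 13 of 13 for each EV library over MAPS, where the median of all genes was negative too. In microglia of IL-4/C1q EV, Hspa1a was at 0.347 and Hspa1b at 0.368 of the UT EV level.

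The 69 most abundant genes (the 50 highest of MAPS and of UT EV combined) held 41.6% of microglial UMIs in UT EV and 30.9% in MAPS. Without them the median log2 ratio of all genes, UT EV over MAPS, was −0.53 instead of −0.61. This value was seen before the test of intron reads took its place among the explanations weighed. Between 37 and 59 barcode sequences were shared by a pair of libraries.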
